A study of Mus musculus with 8 samples.

How the data were processed

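The data were 8 bulk RNA sequencing libraries of mouse sarcoma cells sorted from tumours, 2 in each of the 4 groups sgSCR, sgMif, shSCR and shMif, taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol from cells purified by fluorescence-activated sorting. Library kit, strandedness, read length and the identity of the fluorescent marker are not given in the sources used here. Per the submitters' processing notes, reads were processed with Trimmomatic and Salmon against build mm10. Versions, options and the transcript release of the Salmon index are not given in the sources used here.

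The deposited tables hold, for each of 116546 transcripts, an estimated count of reads (Salmon's NumReads, which need not be whole) and a value in TPM (transcripts-per-million units), per the file headers. The authors' TPM values are relative to effective transcript length and sum to the same total in each library. Each deposited table is 1 library, and no pooled or normalised table was used here. Transcript identifiers were joined to genes through the GENCODE release M21 annotation of mm10, where 115785 matched with their version and 115977 without it. The 569 unmatched transcripts held 0.101 to 0.205% of reads per library and were left out of tests.

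Estimated counts were summed over the transcripts of each of 35498 genes and rounded to whole numbers. Totals of 19042235 to 51819308 reads per library set the precision, so that 3 counts in each sgMif library correspond to a mean of 0.102 CPM. Genes were kept by the filterByExpr function of edgeR 4.0.16 with a minimum count of 10 and a minimum total of 15, which left 16309. Libraries were scaled by the trimmed mean of M values (TMM), and normalised levels are CPM values (counts-per-million units) computed here. Genes were tested with edgeR's quasi-likelihood test in R 4.3.3, with p-values adjusted by the Benjamini-Hochberg method at 0.05. sgMif against sgSCR, shMif against shSCR, their difference and shSCR against sgSCR came from 1 fit of 4 group means with 4 residual degrees of freedom, which share 1 estimate of spread. The joint effect came from an additive fit of system and Mif label with 5 residual degrees of freedom.

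Gene lists were tested with camera in limma 3.58.1 on log2 CPM with the preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. The 35 lists of 660 genes covered tumour programs, signals to immune cells, sorting stress, neighbours of Mif on the chromosome and markers of other cell types that a tumour sort can hold. They were written from general knowledge, and 3 symbols had no match in the annotation. Genes past the threshold were counted per list over all genes tested and with p adjusted over the list alone. The groups, the tests, the gene lists, the rule for named genes and most alternatives were set before the data were examined.

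The genes named are Mif and its family first, then the 12 highest and 12 lowest log2 fold changes among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the arms compared. For the difference of effects and for the control groups they are the 5 highest and 5 lowest. Predicted genes, pseudogenes and small RNA genes were counted and not named, and 2 genes that these rules would name are not reported here. Where fewer than 10 genes passed, the 10 with the smallest p are given as values that did not pass. Up to 4 members with the smallest p are named per list, and any other gene or value singled out was chosen after its values were seen. Folds against a group with 0 reads are bounds against 3 counts in each library of that group, ratios against 1 to 3 reads pool the reads of each group and carry a 95% counting interval, and both cover counting error only. Reads of overlapping, antisense or near-identical genes could be split by the authors' quantification in ways that these tables do not show.

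Alternatives were size factors by relative log expression, DESeq2 1.42.0, no filter on low counts, counts scaled by transcript length, a replicate block, each system fitted alone, the mean of separate contrasts, fry, and leaving out each library in turn. When 1 library of a group was left out, the remaining one was assumed to vary like the other groups. A term for the library class, the replicate number as a term over both systems, protein-coding transcripts only, and the 5 libraries of the high class were added after the data were seen, the last with 1 residual degree of freedom in the fit of group means. The class divides libraries at 1000 CPM over olfactory receptor genes. Genes like Mif in sequence were found with blastn 2.17.0. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

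The fits were tested on simulated data drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold among 16309. The changed genes were drawn from those with a mean log2 CPM above 1, so recovery of less abundant genes was not tested. For sgMif against sgSCR, 17 of the 2-fold and 77 of the 4-fold genes were recovered with 5 false calls. For shMif against shSCR, 29 and 73 were recovered with 14 false calls, and for the joint fit 61 and 93 with 8 false calls. Camera recovered the 1 simulated list that was shifted on purpose, and 4 of 100 unshifted lists had an unadjusted p under 0.05. The simulated genes were drawn independently of each other and put into lists at random, so this run does not test the preset correlation of 0.01. In the real libraries the correlation estimated for sgMif against sgSCR was 0.672 for cholesterol synthesis and 0.738 for type I interferon genes.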

Results

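Bulk RNA sequencing was carried out on sarcoma cells recovered from mouse tumours, to ask how Mif made by the tumour affects pathways inside the tumour cells. Mif encodes macrophage migration inhibitory factor, a secreted cytokine that binds CD74 and signals with CD44, CXCR2, CXCR4 and ACKR3. Per the labels, the sarcoma cells were C57BL/6 mesenchymal stem cells transformed by loss of p53 and overexpression of Ccne1, the gene of cyclin E1. Reads on Trp53, the gene of p53, were present at 72.9 to 126 CPM (counts-per-million units) in the 8 libraries and those on Ccne1 at 8.67 to 20.6 CPM. The part of Trp53 that was lost and the level of Ccne1 before transformation are not given, so these levels do not test the label. The cells carried Cas9 with a guide RNA against Mif (sgMif) or a non-targeting guide (sgSCR), or a short hairpin RNA against Mif (shMif) or a control hairpin (shSCR). Tumours grew under the skin of recipient mice on polyurethane scaffolds, were digested, and the cells were sorted on a fluorescent marker. Each of the 4 groups held 2 libraries. Total estimated counts were 37573433 and 19677400 reads for sgSCR 1 and 2, and 21825188 and 45555554 for sgMif 1 and 2. For shSCR 1 and 2 they were 38542409 and 51819308, and for shMif 1 and 2 they were 19042235 and 36676645. After a filter on low counts, 16309 genes were tested. Nothing in the labels states that the 2 libraries of a group came from separate mice, so p-values measure only the spread between these libraries, which may be technical. The libraries of every group differed by more than counting noise, with a chi-square per degree of freedom of 25.8 for sgSCR, 46.5 for sgMif, 37.5 for shMif and 129 for shSCR.

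The libraries also differed in a way that the groups did not explain. Reads on 1406 olfactory receptor genes, which encode the odorant receptors of the nose, made up 380 CPM in sgMif 2, 553 in shMif 2 and 523 in shSCR 2. In the other 5 libraries they made up 1330 to 2544 CPM. Both sgSCR libraries belonged to these 5, at 2544 and 1418 CPM. This class of library was defined after the data were seen, and the means of called lists within the 5 libraries of the high class stand beside the pooled ones. In those 5, sgMif, shSCR and shMif have 1 library each, so the spread there comes from the sgSCR pair alone, except in the joint fit, where disagreement between the systems adds to it. The share of reads on mitochondrially encoded genes was 1.63% in shSCR 1 and 2.12 to 2.65% in the other 7 libraries, and that of transcripts annotated with a retained intron was 5.42% in shSCR 1 and 3.9 to 4.85% in the others.

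**Figure D1:**
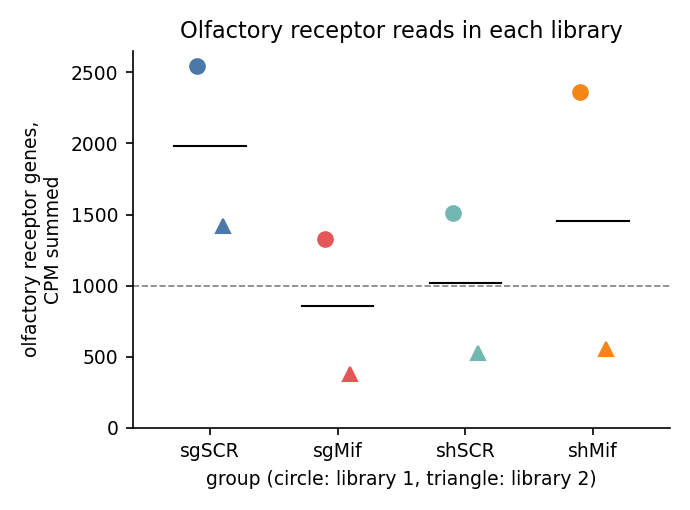
Reads on olfactory receptor genes in each of the 8 libraries, as CPM on the vertical axis, with libraries named by group and replicate on the horizontal axis. The 3 libraries under the dashed line at 1000 CPM are sgMif 2, shMif 2 and shSCR 2, at 380, 553 and 523 CPM.

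Mif itself (ENSMUSG00000033307, chromosome 10, 75859353 to 75860240, minus strand, mm10) was measured first in every library. Its normalised level was 377 and 455 CPM in sgSCR 1 and 2 and 221 and 222 CPM in sgMif 1 and 2. The sgMif mean of 222 ± 0.54 CPM (SD, n = 2) was 1.88-fold lower than the sgSCR mean of 416 ± 55 CPM (SD, n = 2). This log2 fold change of -0.91 ± 0.32 (SE) gave an edgeR adjusted p of 0.215 over all genes tested and 0.0446 with p adjusted over the list alone, the 8 genes of the MIF family and its receptors. DESeq2 gave -0.93 (adjusted p = 0.0287), edgeR on the 4 CRISPR libraries alone gave -0.93 (adjusted p = 0.0384), and the 5 high-class libraries, with 1 of sgMif, gave -0.91. Leaving out shSCR 1 gave an edgeR adjusted p of 0.0296 and leaving out shSCR 2 one of 0.0322. The shSCR libraries, at 170 and 375 CPM, and those labelled shMif, at 277 and 222, also lay below both sgSCR libraries. A fall by the guide thus cannot be told apart from a high level particular to the sgSCR libraries. A guide that shifts the reading frame need not lower the transcript, and the place of the cut within Mif is not given in the sources used here.

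No fall of Mif was detected in the libraries labelled shMif. They held 277 and 222 CPM, a mean of 250 ± 39 (SD, n = 2), against 170 and 375 CPM in shSCR 1 and 2, a mean of 273 ± 140 (SD, n = 2). The log2 fold change was -0.13 ± 0.32 (SE, edgeR adjusted p = 0.925). It was 0.55 without shSCR 2, -0.59 without shSCR 1, 0.02 without shMif 2 and -0.30 without shMif 1. Within the high class, where it compares shMif 1 with shSCR 1 alone, it was 0.70. With all 4 libraries the transcript did not bear out the knockdown label, and these are called the libraries labelled shMif throughout. Among the receptors, Ackr3, a decoy receptor for chemokines, fell 2.06-fold in sgMif cells (log2 fold change -1.04 ± 0.18 SE, edgeR adjusted p = 0.0413). Cxcr4 stood at -1.67 ± 0.52 (adjusted p = 0.165) and Cd44 at 0.43 ± 0.15 (adjusted p = 0.206), and Cd74, Cxcr2, Ddt and Cops5 lay between -0.34 and 0.23. With p adjusted over the list alone, 3 of the 8 fell and 1 rose.

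**Figure D2:**
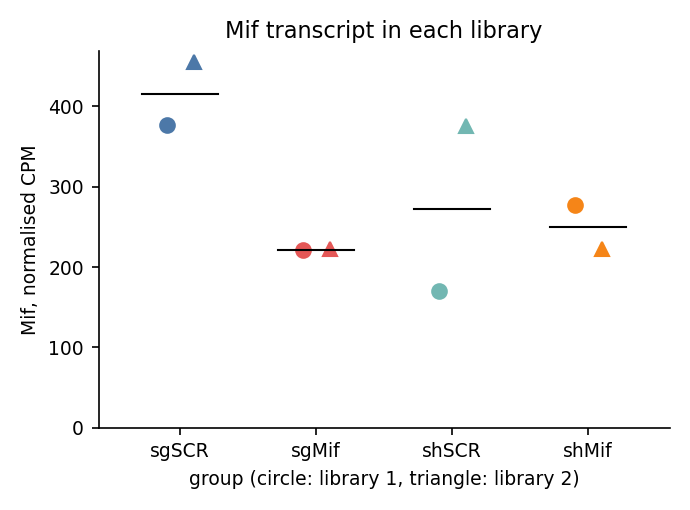
Normalised level of Mif in CPM in each of the 8 libraries, by group on the horizontal axis, with points for libraries and bars for group means. Both sgMif libraries lie at 221 to 222 CPM, below both sgSCR libraries at 377 and 455, while the shSCR libraries at 170 and 375 enclose the libraries labelled shMif at 277 and 222.

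The first comparison, sgMif against sgSCR, asked what the Mif guide did to the sarcoma cells. Genes of cholesterol synthesis rose together. Acat2, which joins acetyl-CoA units at the start of the pathway, rose 3.36-fold (log2 fold change 1.75 ± 0.17 SE, edgeR adjusted p = 0.0148), from 36.7 ± 3.7 to 123 ± 6.6 CPM (SD, n = 2). Pmvk, the kinase of phosphomevalonate, rose 2.81-fold (1.49 ± 0.17, adjusted p = 0.0189), and Msmo1, a sterol demethylase, rose 2.68-fold (1.42 ± 0.19, adjusted p = 0.032). Of 22 members measured, 12 rose and 0 fell over all genes tested, and 21 rose and 0 fell with p adjusted over the list alone. The mean log2 fold change was 1.30 (camera adjusted p = 1.65e-17, adjusted p = 0.324 with an estimated correlation), and 1.33 within the high class.

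Cell division genes rose as well. In the list for mitosis and G2/M, 4 of 25 members rose and 0 fell over all genes tested, and 24 rose and 0 fell with p adjusted over the list alone. Prc1, which bundles spindle microtubules, rose 2.26-fold (1.18 ± 0.19, edgeR adjusted p = 0.0394), Ccnb1, the mitotic cyclin B1, rose 2.27-fold (1.18 ± 0.21, adjusted p = 0.0494), and the proliferation marker Mki67 rose 2.14-fold (1.10 ± 0.19, adjusted p = 0.0481). In the list for G1/S and DNA replication, 6 of 28 rose and 0 fell, with 20 rising and 0 falling when adjusted over the list alone. They included the replicative helicase subunits Mcm6, up 1.94-fold (0.96 ± 0.12, adjusted p = 0.0288), Mcm4, up 1.77-fold, and Mcm3, up 1.87-fold. The mean log2 fold change was 0.85 for G2/M (camera adjusted p = 9.12e-16, adjusted p = 0.281 with an estimated correlation) and 0.66 for G1/S (camera adjusted p = 5.67e-14, adjusted p = 0.253 with an estimated correlation). Within the high class the means were 0.78 and 0.67.

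Stress and oxygen response genes moved the other way. The integrated stress response, the program that the transcription factor ATF4 runs when translation is checked, had negative log2 fold changes in all 20 members, with 5 falling over all genes tested and 12 with p adjusted over the list alone. Cth, which makes cysteine from cystathionine, fell 5.54-fold (-2.47 ± 0.20, edgeR adjusted p = 0.0148), Vldlr, a lipoprotein receptor, fell 4.49-fold (-2.17 ± 0.24, adjusted p = 0.0189), and Sesn2, an inhibitor of mTORC1, fell 2.71-fold (-1.44 ± 0.20, adjusted p = 0.033). The list mean was -0.95 (camera adjusted p = 4.25e-10, adjusted p = 0.253 with an estimated correlation), and -0.91 within the high class. The 2 control groups differed in this list by a similar amount, with shSCR below sgSCR by a mean of -1.02. Of 25 hypoxia genes, 4 fell and 0 rose, with 12 falling and 0 rising adjusted over the list alone. They were the collagen cross-linking enzyme Lox, down 2.21-fold (-1.14 ± 0.16, adjusted p = 0.033), Ndrg1, down 2.64-fold, the oxidase Ero1l, down 2.80-fold, and the glucose transporter Slc2a1, down 2.12-fold. The hypoxia mean was -0.63 (camera adjusted p = 2.85e-08, adjusted p = 0.435 with an estimated correlation), -0.91 within the high class and -0.41 without sgMif 1.

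Genes for signals to myeloid cells were lower in the sgMif than in the sgSCR libraries. The called lists of other cell types fell too, with means of -0.98 for macrophage, -2.28 for B cell and -0.81 for host skin fibroblast markers. Whether sarcoma cells or other sorted cells made the transcripts in this paragraph cannot be told apart here. Among 34 ligands and enzymes known to recruit or polarise myeloid cells, 4 fell and 1 rose over all genes tested, and 19 fell and 2 rose with p adjusted over the list alone. Il33, an alarmin cytokine, fell 6.15-fold (-2.62 ± 0.26, edgeR adjusted p = 0.0148), Ccl11, which attracts eosinophils, fell 10.9-fold (-3.45 ± 0.49, adjusted p = 0.033), and Ptges, which makes prostaglandin E2, fell 2.55-fold (-1.35 ± 0.18, adjusted p = 0.032). Cx3cl1, the ligand of the receptor CX3CR1, rose 2.16-fold (1.11 ± 0.16, adjusted p = 0.033). The mean was -1.14 (camera adjusted p = 1.64e-08, adjusted p = 0.253 with an estimated correlation), and -0.96 within the high class. In the same list shSCR lay below sgSCR by a mean of -1.06. Type I interferon response genes had a mean of -0.69 over 30 members (camera adjusted p = 1.01e-06, adjusted p = 0.584 with an estimated correlation), 0 of which passed over all genes tested and 4 of which fell with p adjusted over the list alone, and the mean was -0.83 within the high class. Oas2, which senses double-stranded RNA, stood at -1.77 ± 0.35 (edgeR adjusted p = 0.0635). The 22 targets of NF-kB had a mean of -0.65 (camera adjusted p = 2.72e-05, adjusted p = 0.369 with an estimated correlation), with 0 members passing over all genes, 6 falling with p adjusted over the list alone, and a high-class mean of -0.54. The NF-kB inhibitor Tnfaip3 stood at -1.26 ± 0.25 (edgeR adjusted p = 0.0647). Of 20 matrix proteases and inhibitors, 1 fell over all genes tested, the macrophage elastase Mmp12, down 3.6-fold (-1.85 ± 0.27, adjusted p = 0.0333), and 8 fell with p adjusted over the list alone. Their mean was -0.90 (camera adjusted p = 3.4e-05, adjusted p = 0.253 with an estimated correlation), and -0.82 within the high class.

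Transcripts of macrophages were present in the sorted cells and were lower in sgMif than in sgSCR. Of 18 macrophage markers, the mannose receptor Mrc1 fell 18.1-fold (-4.18 ± 0.63, edgeR adjusted p = 0.0333), and 8 fell and 0 rose with p adjusted over the list alone. Mrc1 held 107 and 34.0 CPM in sgSCR 1 and 2, 2.01 and 5.59 in sgMif 1 and 2, 15.5 and 12.4 in shSCR 1 and 2, and 18.8 and 13.9 in the libraries labelled shMif. Its fold was 8.83 without sgSCR 1, 27.2 without sgSCR 2 and 34.9 without sgMif 2. Laptm5, a lysosomal protein of blood cells, held 26.1 and 20.9 CPM in sgSCR and 10.3 and 10.2 in sgMif (-1.20 ± 0.25, adjusted p = 0.0719), while the lysozyme gene Lyz2 held 38.2 and 30.3 in sgSCR and 64.5 and 30.6 in sgMif (0.47 ± 0.38, adjusted p = 0.571). The list mean was -0.98 (camera adjusted p = 0.000307, adjusted p = 0.584 with an estimated correlation), -1.10 within the high class and -0.58 without sgSCR 1. Host skin fibroblast markers, 11 genes that mesenchymal tumour cells can also express, had a mean of -0.81 (camera adjusted p = 0.00106, adjusted p = 0.281 with an estimated correlation) and -0.72 within the high class. In this list 1 gene fell over all genes tested, the matrix proteoglycan Dcn, down 4.54-fold (-2.18 ± 0.23, edgeR adjusted p = 0.0149), and 7 fell with p adjusted over the list alone. The 6 B cell markers had a mean of -2.28 (camera adjusted p = 0.00549, adjusted p = 0.41 with an estimated correlation), with 0 members passing over all genes and 1 falling with p adjusted over the list alone. That call was lost with protein-coding transcripts, at -1.51 (adjusted p = 0.108), within the high class, at -1.98 (adjusted p = 0.0654), without sgMif 2, at -1.97 (adjusted p = 0.0582), and without sgSCR 2, at -1.51 (adjusted p = 0.0588).

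Smaller shifts appeared in 4 further lists. The 35 oxidative phosphorylation genes had a mean of 0.25 (camera adjusted p = 0.000163, adjusted p = 0.435 with an estimated correlation) and 0.24 within the high class, and 0 members passed under either adjustment. For the 18 genes of the unfolded protein response the mean was 0.23 (camera adjusted p = 0.0203, adjusted p = 0.482 with an estimated correlation), 0.33 within the high class, again with 0 members passing. It was 0.18 with protein-coding transcripts (adjusted p = 0.108), 0.12 without sgMif 1 (adjusted p = 0.279), 0.26 without sgSCR 1 (adjusted p = 0.051) and 0.23 without sgSCR 2 (adjusted p = 0.0637). Glycolysis genes, 18 in number, had a mean of -0.36 (camera adjusted p = 0.00184, adjusted p = 0.535 with an estimated correlation) and -0.47 within the high class, with 1 falling under each adjustment. It was -0.27 without sgMif 1 (adjusted p = 0.173) and -0.31 without sgSCR 2 (adjusted p = 0.0748). The 20 ERK targets had a mean of -0.34 (camera adjusted p = 0.0378, adjusted p = 0.435 with an estimated correlation) and -0.35 within the high class, with 0 passing over all genes and 5 falling with p adjusted over the list alone. This call was lost without sgMif 1 (adjusted p = 0.105), sgSCR 2 (adjusted p = 0.359), shMif 1 (adjusted p = 0.0676) and shMif 2 (adjusted p = 0.0693), with a mean of -0.19 without sgSCR 2, and with the replicate number as a block within systems (-0.37, adjusted p = 0.154) or as a term over both (-0.35, adjusted p = 0.113). With an estimated correlation, 0 of the 35 lists were called in any comparison.

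**Figure D3:**
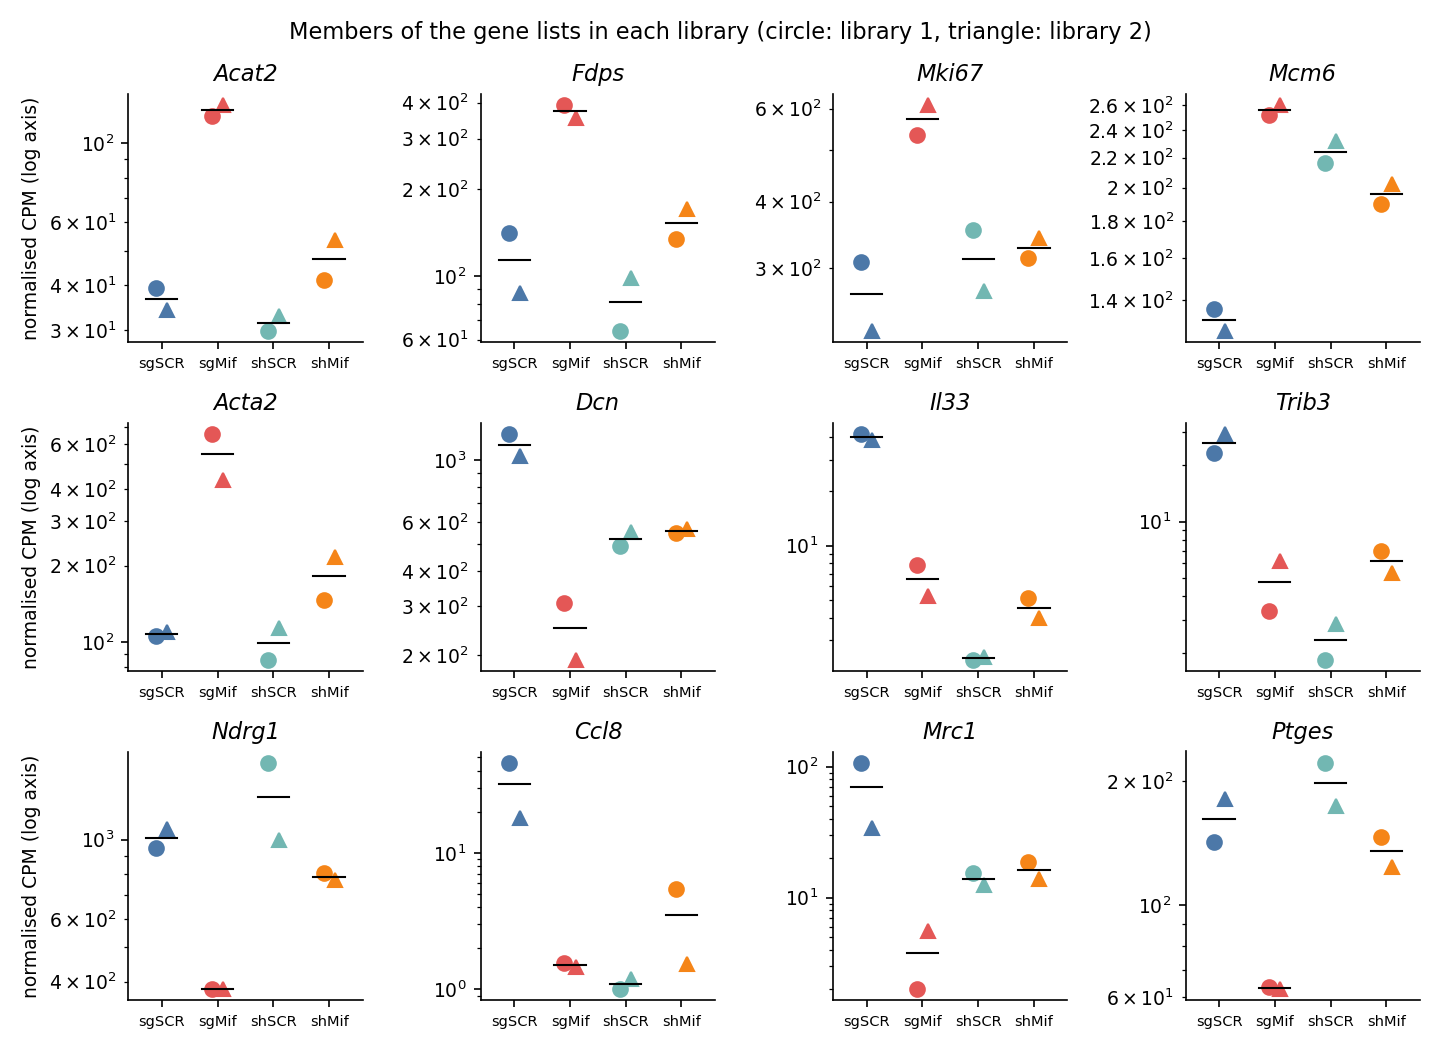
Normalised levels of 12 list members in CPM (log axes) in each of the 8 libraries, by group, with 1 point per library. Acat2, Fdps, Mki67, Mcm6 and Acta2 are higher in both sgMif libraries than in both sgSCR libraries, while Il33, Trib3, Ccl8 and Mrc1 are high in both sgSCR libraries and lower in each of the other 6.

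The genes with the largest changes were named by a rule on size. Acta2, smooth muscle actin, rose 5.06-fold (2.34 ± 0.27 SE, edgeR adjusted p = 0.0196), from 108 ± 2.7 to 547 ± 160 CPM (SD, n = 2), and Tnnt2, cardiac troponin T, rose 5.11-fold (2.35 ± 0.41, adjusted p = 0.0476). The other large rises were of the sterol and lipid genes Idi1, 3.54-fold, Fdps, 3.28-fold, Stard4, 2.90-fold, Hmgcs1, 2.85-fold, and Elovl6, 2.74-fold, and of the growth factor gene Ptn, 2.87-fold. Cd163, a scavenger receptor of macrophages, had 4580 reads in sgSCR, at 63.8 ± 54.9 CPM (SD, n = 2), and 0 in both sgMif libraries, at least 623-fold lower (edgeR adjusted p = 0.0333). Ighg1, an immunoglobulin heavy chain, had 432 reads in sgSCR and 0 in sgMif, at least 78.9-fold lower (adjusted p = 0.0358). Both bounds set 3 counts in each library of the group of 0, and cover counting error only. Chil3, a chitinase-like protein of alternatively activated macrophages, fell 69.0-fold (-6.11 ± 0.78, adjusted p = 0.0288), the chemokine gene Ccl8 fell 21.1-fold (-4.40 ± 0.67, adjusted p = 0.0334), and Rarres2, which encodes the chemoattractant chemerin, fell 13.0-fold (-3.70 ± 0.42, adjusted p = 0.0192). Col6a5 fell 43.8-fold, Cdsn 25.4-fold, Fam213a and Slc12a5 14.3-fold each, Slitrk6 11.5-fold and Ms4a6d 11.4-fold, with adjusted p values of 0.0277 to 0.0437. Slc12a5 held only 0.0913 and 0.0451 CPM in sgMif 1 and 2, so its fold rests on few reads there. For Rarres2, Col6a5 and Ccl8 the shSCR means were about as low, at 3.08, 0.241 and 1.1 CPM against 3.12, 0.215 and 1.51 in sgMif. Cd163, Ighg1, Chil3 and Cdsn were also low in shSCR, and Ms4a6d lay between. Fam213a, Slc12a5 and Slitrk6 were not lower in shSCR than in sgSCR. Falls also seen in shSCR cannot be told apart from a property of the sgSCR libraries. Leaving out 1 library moved some folds by over 1.5 times. Without sgSCR 1 the bound of Cd163 was 244-fold, and the folds of Ccl8 and Ms4a6d were 12-fold and 5.63-fold. Without sgSCR 2 the bound of Cd163 was 1000-fold, and without sgMif 1 it was 943-fold and that of Ighg1 119-fold. The fold of Chil3 was 43.8 without sgMif 1 and 322 without sgMif 2, and that of Fam213a 24.7 and 9.43.

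Across all genes, edgeR called 161 in this comparison, 60 higher and 101 lower in sgMif, 2706 had an unadjusted p under 0.05 where 815 were expected by chance, and DESeq2 called 990. With length-scaled counts edgeR called 15, all among the 161, and with a term for the library class 49, of which 44 were among them. Of the 25 named calls, 4 and 9 held in these 2 settings. Within the high class, with 1 library of sgMif, 534 were called, 143 of them among the 161. Leaving out 1 library gave 2 calls without sgMif 1, 0 without sgMif 2, sgSCR 1 or sgSCR 2, 54 without shMif 1, 39 without shMif 2, 356 without shSCR 1 and 326 without shSCR 2. At an unadjusted p under 0.05, those edgeR fits with 0 calls had 1849, 2038 and 1981 genes, and each single gene called here lost its call when any 1 of the 4 CRISPR libraries was left out, except 1 gene that remained without sgMif 1.

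The second comparison set the libraries labelled shMif against shSCR. By edgeR 3 genes passed, each of them higher in the libraries labelled shMif. Ccn5, a secreted matricellular protein, rose 12.7-fold (3.66 ± 0.27 SE, edgeR adjusted p = 0.00855), from 1.66 ± 0.21 to 21.1 ± 3.9 CPM (SD, n = 2). Itgb4, the integrin of hemidesmosomes, rose 8.58-fold (3.10 ± 0.25, adjusted p = 0.00855), and Vgll3, a cofactor of TEAD transcription factors, rose 5.77-fold (2.53 ± 0.21, adjusted p = 0.00855). The next smallest p values belonged to Mid1 (1.86 ± 0.20, adjusted p = 0.0583), Ptn (1.82 ± 0.23, adjusted p = 0.0999), Aspn (1.91 ± 0.24, adjusted p = 0.0999), Islr (1.85 ± 0.24, adjusted p = 0.106), Mfap4 (2.81 ± 0.37, adjusted p = 0.117), Fbln5 (1.46 ± 0.20, adjusted p = 0.139) and C1qtnf3 (4.11 ± 0.58, adjusted p = 0.149). Itgb4 apart, each gene named here had its lowest group mean in shSCR. Ccn5 held 32.7 CPM in sgSCR and 23.2 in sgMif, and Vgll3 held 28.3 and 52.9, against 6.64 in shSCR. Itgb4 held 39.9 CPM in the libraries labelled shMif and 4.21 to 5.65 in the other groups. Rises from a level low in shSCR alone cannot be told apart from a property of the shSCR libraries. DESeq2 called 182 genes, and 1511 had an unadjusted edgeR p under 0.05. The count was 758 without shSCR 2, 5 without sgMif 1 or shSCR 1, 0 without shMif 2 (1202 at an unadjusted p under 0.05), and 0 genes were called from the 4 shRNA libraries alone (1054 at an unadjusted p under 0.05).

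Of the 35 lists, 14 were called between the libraries labelled shMif and shSCR, 10 higher and 4 lower, each with 0 members passing over all genes tested by edgeR. Cholesterol synthesis rose here too, with a mean of 0.68 over 22 members (camera adjusted p = 6.57e-10, adjusted p = 0.819 with an estimated correlation), 0.64 within the high class and 0.43 without shMif 2. All 22 had positive values and 14 rose with p adjusted over the list alone, among them Insig1, which holds back sterol synthesis (0.80 ± 0.18, edgeR adjusted p over all genes 0.407). Hypoxia genes had a mean of -0.29 (camera adjusted p = 0.000661), -0.39 within the high class and -0.19 without shSCR 1, with 1 rising, Lox (0.77 ± 0.16), and 0 falling when adjusted over the list alone. Glycolysis genes had a mean of -0.29 as well (camera adjusted p = 0.000646) and -0.38 within the high class. Collagen and matrix genes had a mean of 0.44 (camera adjusted p = 0.000661) and 0.45 within the high class, with 5 rising and 2 falling when adjusted over the list alone, and the call was lost without shMif 2, at 0.25 (adjusted p = 0.131). Col1a1 and Col3a1, the fibrillar collagens of connective tissue, stood at 1.36 ± 0.30 (edgeR adjusted p = 0.407) and 1.09 ± 0.26 (adjusted p = 0.417). Each of these lists other than cholesterol synthesis also had an adjusted p = 0.819 with an estimated correlation. In all 4 lists shSCR differed from sgSCR with the opposite sign. The means were -0.23 for cholesterol synthesis, 0.26 for hypoxia, 0.42 for glycolysis and -0.68 for matrix genes. Shifts that mirror this gap cannot be told apart from a property of the shSCR libraries.

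Immune and mitochondrial lists were higher in the libraries labelled shMif. Genes that present antigen on MHC class I had a mean of 0.41 over 18 members (camera adjusted p = 0.000661), 0.62 within the high class, 0.23 without shSCR 1 and 0.61 without shSCR 2. The 13 mitochondrially encoded genes had a mean of 0.56 (camera adjusted p = 9.53e-05), 0.81 within the high class and 0.85 without shSCR 2, beside the lower mitochondrial share of shSCR 1. Host skin fibroblast markers had a mean of 0.56 (camera adjusted p = 0.00443), 0.79 within the high class, with 2 rising when adjusted over the list alone, among them Pi16 (1.28 ± 0.25). For these 3 lists the adjusted p = 0.819 with an estimated correlation. Type I interferon genes had a mean of 0.31 (camera adjusted p = 0.00443, adjusted p = 0.84 with an estimated correlation), 0.92 within the high class, 0.20 without shMif 1 (adjusted p = 0.0708), -0.06 without shSCR 1 (adjusted p = 0.361) and 0.83 without shSCR 2. The myeloid ligand list had a mean of 0.32 (camera adjusted p = 0.0407, adjusted p = 0.819 with an estimated correlation), with 6 rising and 2 falling when adjusted over the list alone. Its call was lost without shMif 1, at -0.03 (adjusted p = 0.834), and without shSCR 2, at 0.31 (adjusted p = 0.267), with the replicate number as a block, at 0.32 (adjusted p = 0.0713), and with a term for the library class, at 0.31 (adjusted p = 0.0918), and the mean was 0.51 both without shMif 2 and within the high class. The macrophage markers had a mean of 0.33 and were not called (camera adjusted p = 0.201), with 17 of 18 positive. Other immune cell markers were not called either. Those of monocytes and dendritic cells had a mean of 0.47 (camera adjusted p = 0.0527), with 13 of 13 positive, and those of T and NK cells 0.78 (0.109), with 15 of 17 positive. B cell markers stood at 1.28 (0.33) and neutrophil markers, the other way, at -0.41 (0.537). Of the lists called here, shSCR lay below sgSCR for mitochondrially encoded genes (-0.49), fibroblast markers (-0.56, median 0.12) and myeloid ligands (-1.06). It lay slightly above for MHC class I (0.07) and interferon genes (0.14). Rises in lists that were low in shSCR cannot be told apart from a property of the shSCR libraries.

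The third comparison asked what sgMif and the libraries labelled shMif shared, with the system as a term in the fit. Since the hairpin label was not borne out by Mif itself, its direction rests on labels alone for those libraries. Cholesterol synthesis rose in the joint fit, with a mean of 0.99 over 22 members (camera adjusted p = 7.99e-25, adjusted p = 0.472 with an estimated correlation), and 21 rose with p adjusted over the list alone. Mitotic genes had a mean of 0.53 (camera adjusted p = 3.86e-15, adjusted p = 0.472 with an estimated correlation), with 17 of 25 rising when adjusted over the list alone, among them Kif20a, a kinesin of cell division (0.66 ± 0.13). Replication genes had a mean of 0.37 (camera adjusted p = 7.4e-10, adjusted p = 0.581 with an estimated correlation), all 28 positive and 0 passing over the list alone. Hypoxia genes had a mean of -0.46 (camera adjusted p = 4.07e-12, adjusted p = 0.472 with an estimated correlation), with 11 of 25 falling when adjusted over the list alone, among them Slc2a1 (-0.88 ± 0.16) and Ndrg1 (-1.07 ± 0.19). Glycolysis genes had a mean of -0.33 (camera adjusted p = 1.98e-07, adjusted p = 0.472 with an estimated correlation) and matrix proteases one of -0.53 (camera adjusted p = 0.000148, adjusted p = 0.472 with an estimated correlation), with 3 and 6 falling when adjusted over the list alone. Within the high class these 6 means were 1.04, 0.50, 0.43, -0.68, -0.43 and -0.58. Replication genes and proteases were not called in the libraries labelled shMif, at 0.08 (camera adjusted p = 0.516) and -0.16 (camera adjusted p = 0.363), so their joint means rest on the CRISPR arm. Mitotic genes had a mean of 0.85 in sgMif and 0.21 in the libraries labelled shMif, the latter 0.07 without shMif 2 and 0.11 within the high class. Most of their joint mean thus comes from the CRISPR arm.

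Single genes did not pass in the joint fit. edgeR called 0 genes, 1306 had an unadjusted p under 0.05, and DESeq2 called 279. The smallest adjusted p was 0.0616 for Ptn (1.67 ± 0.17). Behind it, at 0.133, came Itgbl1 (0.96 ± 0.13), Islr (1.51 ± 0.20), Ereg (-1.09 ± 0.15), Plin2 (-1.0 ± 0.14), Fam210b (1.04 ± 0.15), Insig1 (0.91 ± 0.13), Sc5d (0.87 ± 0.13) and Bche, which had 0 reads in both sgSCR libraries. Leaving out shSCR 1 or shSCR 2 gave 1 call each, and the mean of the separate contrasts in place of the joint fit gave 66. The other 6 lists called in the joint fit had smaller means. They were the contractile genes (0.27, camera adjusted p = 0.0185, adjusted p = 0.472 with an estimated correlation), the myeloid ligands (-0.43, 0.00539), the NF-kB targets (-0.23, 0.00539), the integrated stress response (-0.32, 0.00657), the mitochondrially encoded genes (0.28, 0.00689) and the matrix genes (0.18, 0.00801). For the last 5 the adjusted p = 0.828 with an estimated correlation. The myeloid, NF-kB and stress means average opposite signs, at -1.14, -0.65 and -0.95 in sgMif and 0.32, 0.19 and 0.33 in the libraries labelled shMif, and so show no shared effect. The matrix list, at -0.07 and 0.44, and the mitochondrial list, at 0.00 and 0.56, were not called in sgMif, so their joint means rest on the libraries labelled shMif. Within the high class all but the matrix list lost the call, at 0.34 (adjusted p = 0.083), -0.31 (0.083), -0.10 (0.181), -0.30 (0.0623) and 0.29 (0.0704). Left-out libraries ended the calls as well. These were sgSCR 1 for the contractile list (0.20), whose call also ended with length-scaled counts (0.22) and protein-coding transcripts (0.24), and shMif 2 for the matrix list (0.08). They were shSCR 1 for the mitochondrial list (0.16), sgMif 2 and both sgSCR libraries for the myeloid list (-0.13, -0.28 and -0.38) and for the NF-kB list (-0.09, -0.14 and -0.21), and each CRISPR library for the stress list, at -0.13 to -0.28. Without shMif 1 the myeloid and NF-kB means were -0.67 and -0.39, without shSCR 2 the myeloid mean was -0.68, without shSCR 1 the stress and matrix means were -0.50 and 0.07, and without sgMif 2 the matrix mean was 0.30.

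The fourth comparison tested the difference between the 2 effects, sgMif against sgSCR minus shMif against shSCR. It also takes in any gap between the 2 control groups, so a call here need not mean 2 different effects of Mif loss. Nes, the intermediate filament nestin, was the 1 gene with a higher effect in the CRISPR arm (1.48 ± 0.18, edgeR adjusted p = 0.0487). Lower effects were seen for Rarres2 (-5.04 ± 0.57, adjusted p = 0.0471), Ccn5 (-4.16 ± 0.36, adjusted p = 0.0375), Chil3 (-8.35 ± 1.01, adjusted p = 0.0471), the chemokine gene Cxcl5 (-7.68 ± 0.96, adjusted p = 0.0487) and Cdsn (-9.27 ± 0.97, adjusted p = 0.0375), the last resting on 1 read in shSCR. Without single libraries some of these moved, Chil3 to -7.68 (sgMif 1) and -10.6 (sgMif 2), Cxcl5 to -6.95 (sgSCR 1) and Cdsn to -8.57 (shSCR 1) and -11.2 (shSCR 2). The gap between the control groups, shSCR against sgSCR, was itself -9.47 for Cdsn and -7.06 for Cxcl5. Ccn5 held 23.2 CPM in sgMif and 21.1 in the libraries labelled shMif, against 32.7 in sgSCR and 1.66 in shSCR. Chil3 held 0.203 CPM in sgMif and 2.55 in the libraries labelled shMif, and so differed there too. Cxcl5 held only 0.0519 and 0.0404 CPM in shSCR 1 and 2, so its value rests on few reads. In all, 15 genes were called, 1 higher and 14 lower, 2571 had an unadjusted p under 0.05, and DESeq2 called 654. With length-scaled counts and with protein-coding transcripts edgeR called 0, with 2359 and 2148 genes at an unadjusted p under 0.05. The count was 6 without sgMif 1, 527 without shSCR 2 and 0 by edgeR without any 1 of sgMif 2, sgSCR 1, sgSCR 2, shMif 1 or shMif 2, where 1338 to 2742 genes had an unadjusted p under 0.05. Across the 16309 genes the 2 sets of log2 fold changes had a Pearson correlation of -0.134 and a Spearman correlation of -0.156, where genes are not independent replicates. Of 9 arrangements of the labels within each system, 4 gave a correlation as large in size, up to 0.379, and the smallest p that the arrangements allow is 0.111. Of the 161 genes called for sgMif, 100 (62.1%) had the same sign in the libraries labelled shMif, and 0 were called in both, where 0.011 were expected.

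**Figure D4:**
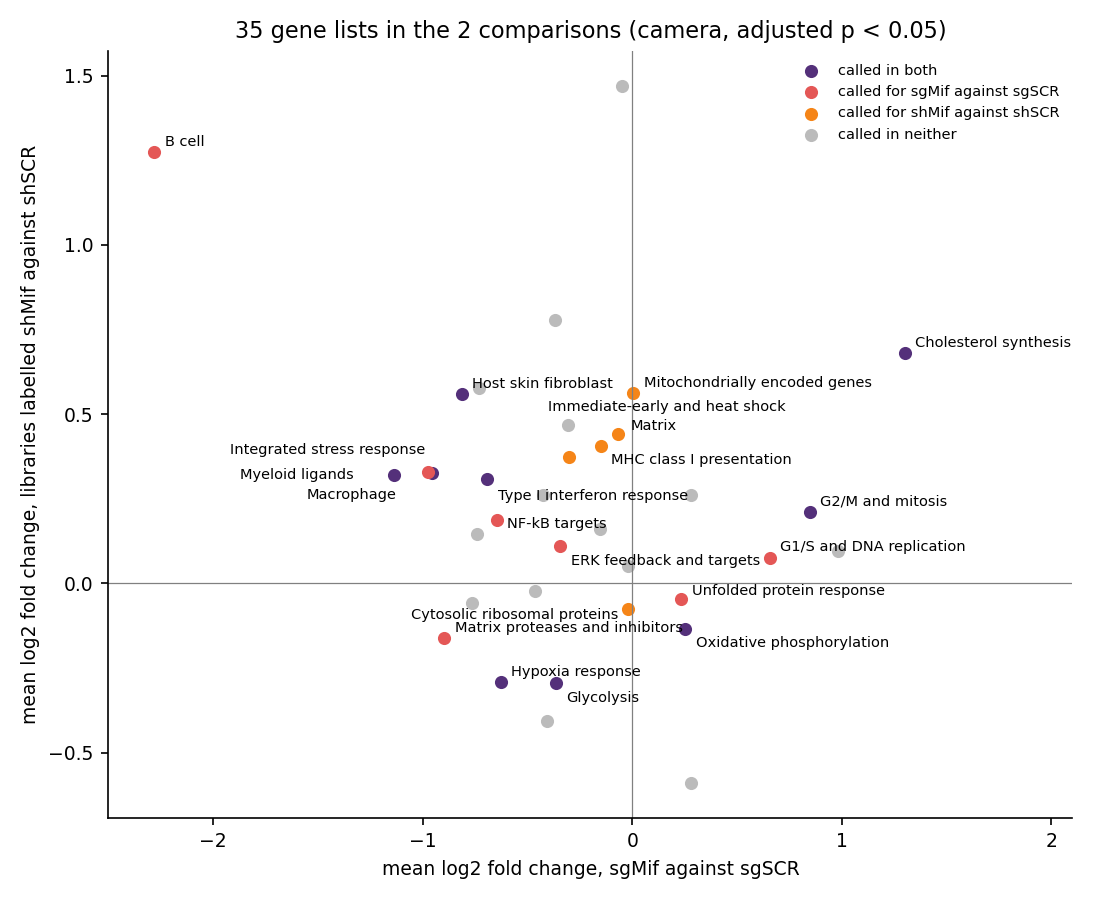
Mean log2 fold change of each of the 35 gene lists for sgMif against sgSCR (horizontal) and for the libraries labelled shMif against shSCR (vertical), coloured by whether camera with its preset correlation called the list in both comparisons, in 1 of them or in neither. Cholesterol synthesis lies high in both, at 1.30 and 0.68, hypoxia and glycolysis lie low in both, and the integrated stress response lies at -0.95 and 0.33.

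The last comparison set the 2 control groups side by side, shSCR against sgSCR, which differ in system and in whatever else separated the experiments. Ligand and stress genes were lower in shSCR. Il33 fell by 4.07 ± 0.28 on the log2 scale (edgeR adjusted p = 0.0013), Cth fell by 2.79 ± 0.20 (adjusted p = 0.00132), and Trib3, a pseudokinase induced by stress, fell by 3.48 ± 0.39 (adjusted p = 0.00604). The integrated stress response list had 10 members lower and 0 higher over all genes tested, and 15 lower and 0 higher with p adjusted over the list alone (mean -1.02, camera adjusted p = 5.11e-07). The myeloid ligands had 9 lower and 1 higher, or 12 and 2 adjusted over the list alone (mean -1.06, camera adjusted p = 0.00149), and the matrix genes 6 lower and 2 higher, or 11 and 2 adjusted over the list alone (mean -0.68, camera adjusted p = 0.000601). Glycolysis (mean 0.42, camera adjusted p = 0.000743) had 3 members higher and 8 with p adjusted over the list alone. The unfolded protein response (mean 0.39, camera adjusted p = 0.00149) had 2 higher and 9 adjusted over the list alone, among them the chaperone gene Hspa5 (0.94 ± 0.14, edgeR adjusted p = 0.0163). For each of these 5 lists the adjusted p = 0.879 with an estimated correlation, and within the high class their means were -1.09, -1.05, -0.87, 0.49 and 0.37.

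edgeR called 655 genes between the control groups, 363 higher and 292 lower in shSCR, against 1948 by DESeq2 and 3738 at an unadjusted p under 0.05. With length-scaled counts it called 287, of which 247 were among the 655. Grpr, the receptor of gastrin-releasing peptide, was 24.6-fold higher in shSCR (4.62 ± 0.47 SE, adjusted p = 0.00454) and the tight junction gene Cldn1 15.5-fold higher (3.96 ± 0.39, adjusted p = 0.00399). Vnn1 was 11.5-fold higher, Ip6k3 was higher by 3.32 on the log2 scale, and Klhl4, with 1 read in sgSCR, had a ratio of 93.0 with a counting interval of 16.4 to 3700.0. Cacna1g, a calcium channel gene, was 110-fold lower (-6.79 ± 0.46, adjusted p = 0.0013), Cxcl5 133-fold, Cd163 219-fold and Moxd1 54.6-fold lower, and Cdsn, with 1 read in shSCR, had a ratio of 851 with a counting interval of 152 to 33700. Cxcl5 held only 0.0519 and 0.0404 CPM in shSCR 1 and 2, so its fold rests on few reads there. Without sgSCR 1 the folds of Cxcl5, Cd163, Moxd1 and Vnn1 were 81.3, 80.7, 35 and 17.9, and without sgSCR 2 that of Cd163 was 338. Without shSCR 1 those of Cd163 and Moxd1 were 2640 and 35.9, and without shSCR 2 those of Cacna1g, Cd163 and Moxd1 were 186, 106 and 123. The log2 fold change of Klhl4 was 6.23, and 4.91 and 8.85 without sgSCR 1 and 2, and that of Cdsn was -9.47, and -8.77 and -11.4 without shSCR 1 and 2. The count of calls was 89 without sgSCR 1, 60 without sgSCR 2, 311 without shMif 1, 281 without shMif 2, 163 without shSCR 1 and 1848 without shSCR 2.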

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

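The tests of the share of macrophages, of the library class, of Mif pseudogenes, of protein-coding transcripts and of the replicate number as a term over both systems were chosen only after the result was seen, and the other tests in this part were planned.

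Results stand here because the sgMif effect and the effect in the libraries labelled shMif differed by a test of the difference itself. That test also takes in the gap between shSCR and sgSCR, so a difference need not mean 2 different effects of Mif loss. Of single genes, 15 differed by edgeR, and 0 with length-scaled counts or with protein-coding transcripts (2359 and 2148 at an unadjusted p under 0.05). Nes had a difference of 1.48 on the log2 scale, Cdsn of -9.27, Chil3 of -8.35, Cxcl5 of -7.68, Rarres2 of -5.04 and Ccn5 of -4.16. The count was 0 by edgeR without sgMif 2, sgSCR 1, sgSCR 2, shMif 1 or shMif 2, with 1338 to 2742 genes at an unadjusted p under 0.05, 6 without sgMif 1 and 527 without shSCR 2, and DESeq2 called 654 with all libraries. Without sgMif 1 and 2 Chil3 was at -7.68 and -10.6, without shSCR 1 and 2 Cdsn was at -8.57 and -11.2, and without sgSCR 1 Cxcl5 was at -6.95.

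Of the gene lists, 18 differed by camera with its preset correlation, and 0 with an estimated one, where the adjusted p values were 0.362 to 0.771. Higher in the CRISPR arm were G1/S genes (0.58), G2/M genes (0.64), cholesterol synthesis (0.62), oxidative phosphorylation (0.39) and the unfolded protein response (0.28). Lower in the CRISPR arm were the integrated stress response (-1.28), myeloid ligands (-1.46), type I interferon genes (-0.999), NF-kB targets (-0.83), host skin fibroblast markers (-1.37), macrophage markers (-1.31), B cell markers (-3.56) and monocyte and dendritic cell markers (-0.77). So were MHC class I genes (-0.56), immediate-early and heat shock genes (-0.68), hypoxia genes (-0.34), mitochondrially encoded genes (-0.56) and matrix proteases (-0.74). Leaving out single libraries ended 8 of these calls. Without sgMif 1 they were MHC class I (-0.35), immediate-early (-0.61), hypoxia (-0.08), unfolded protein response (0.20) and monocyte (-0.49). Without sgMif 2 it was B cell (-2.73), and without sgSCR 1 B cell (-2.71) and monocyte (-0.41). Without sgSCR 2 they were immediate-early (-0.65), hypoxia (-0.18), unfolded protein response (0.31), proteases (-0.43) and B cell (-2.26). Without shMif 1 they were immediate-early (-0.50), monocyte (-0.34) and B cell (-1.67), and without shMif 2 hypoxia (-0.31), mitochondrial (-0.51) and proteases (-0.70). Without shSCR 1 they were mitochondrial (-0.38) and monocyte (-0.38), and without shSCR 2 hypoxia (-0.24), unfolded protein response (0.27), proteases (-0.64) and B cell (-2.84). Calls that held moved by over 1.5 times for interferon, to -0.62 without shSCR 1 and -1.52 without shSCR 2, and for macrophage markers, to -0.72 without shMif 1. The same was true of immediate-early genes, at -1.05 without shSCR 2, of hypoxia genes, at -0.57 without sgMif 2, and of the unfolded protein response, at 0.42 without sgMif 2. Within the 5 libraries of the high olfactory class the calls of proteases (-0.54, adjusted p = 0.202) and B cell markers (-2.78, adjusted p = 0.326) ended. Means moved by over 1.5 times there for interferon (-1.75), MHC class I (-1.004), immediate-early (-1.31), hypoxia (-0.52), mitochondrial (-0.94), macrophage (-1.995) and monocyte genes (-1.53). The other 9 means there were 0.59 for G1/S, 0.67 for G2/M, 0.69 for cholesterol synthesis, 0.43 for oxidative phosphorylation, 0.38 for the unfolded protein response, -1.37 for the stress response, -1.465 for myeloid ligands, -0.965 for NF-kB targets and -1.51 for fibroblast markers. A term for the class ended the monocyte call (-0.81, adjusted p = 0.0816). The replicate number as a block ended those of immediate-early (-0.76, adjusted p = 0.0577), hypoxia (-0.37, adjusted p = 0.0829) and monocyte genes (-0.71, adjusted p = 0.0835), and as a term over both systems it ended those of hypoxia (-0.35) and monocyte genes (-0.75). Protein-coding transcripts ended those of the unfolded protein response (0.26) and B cell markers (-2.71), and length-scaled counts that of proteases (-0.70). The gap between the control groups, shSCR against sgSCR, was itself -1.02 for the stress response and -1.06 for myeloid ligands. For G2/M, cholesterol synthesis, interferon, macrophage, monocyte, MHC class I and hypoxia genes that gap had the sign opposite to the difference.

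The first pattern weighed is the lower level of macrophage transcripts in sgMif than in sgSCR cells. A smaller share of macrophages among the sorted cells would lower all their markers alike only if no other sorted cell made them. The 18 log2 fold changes ran from -4.18 for Mrc1 to 3.20 for Cx3cr1 and were unequal (Cochran's Q 84.0 against a chi-square distribution with 17 degrees of freedom, p = 7.37e-11 for n = 18 markers, and p = 0.000149 for the n = 12 abundant ones without Mrc1). That test takes the errors as known, though they rest on 2 libraries per group. Reads of other cells would also make the falls unequal, so a smaller share is not excluded. A difference between library classes would bring the list to about 0 within the high class, where its mean was -1.10. A change in the kind of macrophage that passed the sort, with fewer cells rich in Mrc1, Cd163 and Chil3, may account for the pattern as a hypothesis, and was not tested against a separate cell count. The high values of these genes in sgSCR relative to all other groups, shSCR included, stay open as a property of the sgSCR tumours rather than of the Mif guide, and 2 libraries per group cannot settle it.

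The second pattern weighed is the level of Mif in the libraries labelled shMif. Reads shared with Mif pseudogenes could mask a knockdown. The 6 genes like Mif in sequence held at most 0.259% of Mif's level in any library. Pseudogene reads that the quantification assigned to Mif itself would not show in that share, so masking is not excluded. A label swapped among the 4 shRNA libraries was expected to give another arrangement more calls and a lower Mif in its own arm, and the values disagree. The 2 other arrangements called 0 genes by edgeR (920 and 208 at an unadjusted p under 0.05) against 3 as labelled (1511 at an unadjusted p under 0.05), and DESeq2 was not run on them. However, Mif parted by 0.735 on the log2 scale when shMif 1 and shSCR 2 were set against shMif 2 and shSCR 1, against -0.127 as labelled. As 1 of 3 arrangements parts a gene most by design, and a knockdown with few effects would call few genes, neither value settles it and a swap stays open. A hairpin with little effect on the transcript after growth in mice, an effect on protein alone, or a single wrong label with no partner stay open as hypotheses. No biological explanation was tested here.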

How the results depend on the processing

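The terms for library class and for the replicate number over both systems, the high class alone and protein-coding transcripts were tests chosen only after the result was seen, and all others were planned. Over 5 counts of called genes, 30 of 87 alternative values stayed within 1.5 times the reported count and 57 moved. Over 84 values of single genes, 1112 of 1485 alternative values kept direction and side of the threshold, 89 gained a call, 249 lost it and 35 changed sign. Over lists, 977 kept their call, 182 lost it and 5 changed sign. Of the 25 named sgMif calls, all held with relative log expression factors, DESeq2, no filter, the replicate block and the number term, 24 within the high class, 22 with the CRISPR libraries alone, 21 with protein-coding transcripts, 9 with the class term and 4 with length-scaled counts. Changes of scaling moved the median gene by at most 0.042 in size. Except where fewer libraries or a tool's own test enter, the cause was not tested.

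In the high class every group but sgSCR has 1 library, so its counts rest on the spread of that pair, except in the joint fit, where disagreement between the systems adds to it. For sgMif against sgSCR (161 calls) the count was 990 with DESeq2, 1494 without a filter, 15 with length-scaled counts, 49 with the class term, 534 in the high class and 0 to 356 leaving out 1 library. For shMif against shSCR (3) it was 182, 662, 5, 7 and 1162 in the same order, 0 to 758 leaving out 1 library, and 0 with the shRNA libraries alone. For the joint effect (0) it was 279 with DESeq2, 549 without a filter, 66 as the mean of separate contrasts, and 0 to 1 leaving out 1 library. For the difference of effects (15) it was 654 with DESeq2, 1306 without a filter, 0 with length-scaled counts, 0 with protein-coding transcripts, 999 in the high class and 0 to 527 leaving out 1 library. For the control groups (655) it was 1948, 2425, 287 and 2747 with DESeq2, no filter, length-scaled counts and the high class, and 60 to 1848 leaving out 1 library. Counts of 0 are by edgeR, with 1054 genes at an unadjusted p under 0.05 for the shRNA libraries alone, 2359 for length-scaled counts and 2148 for protein-coding transcripts.

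Mif in sgMif passed with DESeq2 (-0.929), no filter (-0.891), the CRISPR libraries alone (-0.925) and the high class (-0.911), and lay at -1.043 to -0.749 leaving out 1 library. In the libraries labelled shMif it changed sign in the high class (0.704) and lay at -0.593 to 0.553 leaving out 1 library, and in the joint fit at -0.192 and -0.78 to -0.36 in the same order. Other changes of sign of single genes were of values that did not pass. Cxcr2 in sgMif was 0.071 with the class term, 0.188 in the high class and -1.149 to 0.314 leaving out 1 library, and in the joint fit 0.137, 0.136 and -0.369 to 0.189. Ackr3 in shMif was 0.146 in the high class and -0.378 to 0.043 leaving out 1 library. Ddt in the joint fit was 0.029 with the class term, 0.093 in the high class and -0.13 to 0.035 leaving out 1 library. Cops5 in the joint fit was 0 without a filter, -0.001 length-scaled, -0.022 with the class term, -0.004 in the high class and -0.084 to 0.076 leaving out 1 library. Leaving out 1 library, Cd74 ranged from -0.577 to 0.039 in sgMif, -0.136 to 1.037 in shMif and -0.194 to 0.351 in the joint fit, and in shMif Ddt from -0.108 to 0.279 and Cxcr2 from -0.339 to 0.789. Of called lists, the interferon list in shMif ranged from -0.064 to 0.831, the myeloid list from -0.032 to 0.512 and the ribosomal list from -0.193 to 0.088, the last at 0.006 with protein-coding transcripts and 0.012 in the high class. Fry, which asks whether a list's genes move on balance 1 way, called 7 lists for sgMif, 4 for the difference of effects, 1 for the control groups, and 0 for shMif (4 at an unadjusted p under 0.05) and the joint effect (7 at an unadjusted p under 0.05).

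With the replicate block the counts were 263 for sgMif, 14 for shMif and 50 for the difference, with 2 residual degrees of freedom. For the joint effect, whose fit has fewer terms, the count was 0 by edgeR (1140 at an unadjusted p under 0.05). The block ended the calls of the ERK list in sgMif, of the myeloid, immediate-early and ribosomal lists in shMif, and of the immediate-early, hypoxia and monocyte lists in the difference. Deviations of same-numbered libraries correlated at 0.154 to 0.371 over 6 pairs of groups, but nothing in the labels says that a number marks a shared mouse or day, and each system has only 2 numbers. A block within systems takes up the difference between the control groups. The number as 1 term over both systems gave 459 calls for sgMif, 10 for shMif, 0 for the joint effect (1364 at an unadjusted p under 0.05), 68 for the difference and 994 for the control groups.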

Other observations

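The tests of the library class, of protein-coding transcripts, of the replicate number as a term over both systems and of other splits of the libraries were chosen only after the result was seen, and the other tests in this part were planned.

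Some further genes were lower in sgMif than in sgSCR, and were chosen after their values were seen. Arg1, which breaks down arginine, held 121 and 62.2 CPM in sgSCR 1 and 2, 9.91 and 16.3 in sgMif 1 and 2, 72.9 and 48.2 in shSCR 1 and 2, and 105 and 66.2 in the libraries labelled shMif. It fell by 2.80 ± 0.42 on the log2 scale in sgMif against sgSCR (edgeR adjusted p = 0.0333). Nos2, the inducible nitric oxide synthase that draws on the same substrate, fell by 2.74 ± 0.32 (adjusted p = 0.0199), and Hmox1, heme oxygenase, fell by 2.43 ± 0.37 (adjusted p = 0.0333). Ccl24, an eosinophil chemokine, held 8.68 and 5.33 CPM in sgSCR and at most 0.721 CPM in each of the other 6 libraries. The calls of Arg1, Nos2 and Hmox1 were each among those lost when any 1 CRISPR library was left out. Whether sarcoma cells or macrophages in the sort made these transcripts cannot be told apart here.

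Other gene groups were not called for sgMif against sgSCR. Of 21 p53 target genes, measured in cells that the labels give as p53-/-, 2 fell over all genes and over the list alone, the cell cycle inhibitor gene Cdkn1a (-1.42 ± 0.20, edgeR adjusted p = 0.033) and Sesn2, and the list mean was -0.16 (camera adjusted p = 0.837). Contractile and TGF-beta target genes had a mean of 0.28 (camera adjusted p = 0.105), with 1 rising, Acta2, and 9 rising and 1 falling with p adjusted over the list alone. Collagens and matrix genes had a mean of -0.07 and a median of 0.25 (camera adjusted p = 0.837), with Dcn, Lox and Fbln2 falling. The 18 neighbours of Mif on the chromosome had a mean of -0.74 (camera adjusted p = 0.105), with 0 passing over all genes by edgeR and 3 falling with p adjusted over the list alone, of which Gstt4 stood at -3.21 ± 0.58 (edgeR adjusted p = 0.0502). Camera adjusted p values of 0.154 to 0.898 were found for MHC class I (-0.15), immediate-early and heat shock genes (-0.30), mitochondrially encoded genes (0.00), ribosomal proteins (-0.02), lineage regulators (-0.02) and the MIF family (-0.46). The same range held for markers of monocytes and dendritic cells (-0.31), neutrophils (-0.41), T and NK cells (-0.37), endothelium (0.98), pericytes (-0.42, median 0.23), erythroid cells (-0.05), epithelium (-0.76), adipocytes (-0.73) and skeletal muscle (0.28).

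In the libraries labelled shMif, 5 called lists remain to be given, each with 0 members passing over all genes by edgeR and an adjusted p = 0.819 with an estimated correlation. In each of the 5, shSCR differed from sgSCR with the opposite sign, by -1.02, -0.24, 0.25, -0.47 and 0.05 in the order given below. The integrated stress response had a mean of 0.33 (camera adjusted p = 0.00739), lost without shMif 1 (0.22) and shSCR 2 (0.40), and 0.465 within the high class. G2/M genes had a mean of 0.21 (camera adjusted p = 0.0201), lost without shMif 2 (0.07), without shSCR 2 (0.25) and within the high class (0.11), and 0.33 without shMif 1. Oxidative phosphorylation had a mean of -0.13 (camera adjusted p = 0.0206), lost without shMif 1 (-0.04), without shSCR 2 (-0.08) and with protein-coding transcripts (-0.06), -0.25 without shMif 2 and -0.19 within the high class. Immediate-early and heat shock genes, which cell sorting can induce, had a mean of 0.37 (camera adjusted p = 0.0336), lost without shMif 1 (0.20), without shSCR 1 (0.16), with the replicate block (0.44), with the replicate number as a term over both systems (0.41), with a term for the library class (0.43), with length-scaled counts (0.26) and with protein-coding transcripts (0.36), 0.75 without shSCR 2 and 0.89 within the high class. Ribosomal protein genes had a mean of -0.08 (camera adjusted p = 0.0458), lost without shMif 1 (-0.01), without shSCR 2 (0.09), with the replicate block (-0.05), with relative log expression factors (-0.05), with protein-coding transcripts (0.01) and within the high class (0.01), and -0.16 without shMif 2 and -0.19 without shSCR 1.

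Between the control groups, 4 further lists were called, with an adjusted p of 0.879 to 0.911 with an estimated correlation. Oxidative phosphorylation was higher in shSCR (0.25, camera adjusted p = 0.00476), with 3 members rising and 8 adjusted over the list alone, and the call was lost without shSCR 2 (0.21), with protein-coding transcripts (0.18) and within the high class (0.20, adjusted p = 0.0532). Mitochondrially encoded genes were lower (-0.49, camera adjusted p = 0.0101), a call lost without shSCR 1 (-0.31), -0.77 without shSCR 2 and -0.78 within the high class. NF-kB targets were lower (-0.48, camera adjusted p = 0.0397), with 2 falling, or 5 falling and 1 rising adjusted over the list alone, and lost without sgMif 1 (-0.45), sgMif 2 (-0.45), sgSCR 1 (-0.37), sgSCR 2 (-0.50) or shSCR 2 (-0.53), within the high class (-0.53, adjusted p = 0.141), with the class term (-0.37), with the replicate number as a term (-0.46), with length-scaled counts (-0.36) and with protein-coding transcripts (-0.50). Hypoxia genes were higher (0.26, camera adjusted p = 0.0426), with 2 rising and 1 falling, or 4 and 2 adjusted over the list alone, lost without sgSCR 1 (0.18), without shSCR 1 (0.16), with the class term (0.21) and with protein-coding transcripts (0.22), 0.40 without sgSCR 2 and 0.35 within the high class.

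The third pattern weighed is the division of the libraries by reads on olfactory receptor genes. If the class were the whole cause of the sgMif calls, a term for it would take up their changes. With that term the log2 fold changes of the 161 genes had a median of 0.951 times their values without it (quartiles 0.917 and 0.991), all 161 with the same sign. These genes were called on a small spread within groups, and sgMif, shSCR and shMif each pair a high-class with a low-class library. A gene that follows the class would differ within those pairs and could hardly be called. The ratio with the class term was thus nearly fixed by this selection, and no conclusion on the class is drawn from it. The term ended 117 of the 161 calls, whose median size was 1.196 without it and 1.158 with it, at a median SE of 0.184 and 0.2, so the calls ended with a wider error, 1 fewer residual degree of freedom and slightly smaller changes. Reads from genomic DNA would spread over the receptor genes, and the 10 genes with most reads held 37.4% of them. That lay between the limits set for this test, under 20% for genomic DNA and over 50% against it. The same 10 genes held 36.5 to 41.1% in the libraries of the high class and 24.5 to 33.7% in those of the low class. Reads on 556 vomeronasal receptor genes divided the libraries alike. They made up 170 CPM in sgMif 2, 220 in shMif 2 and 206 in shSCR 2, and 531 to 1052 CPM in the other libraries. What raised them together was not tested, so genomic DNA could not be excluded or shown. Pecam1, an endothelial gene, had 75.1 to 97.6% of its reads in a transcript with a retained intron, and its level is read here with that limit. That level followed the same division, at 24.4, 35.5 and 19.9 CPM in sgMif 2, shMif 2 and shSCR 2, and 111.9 to 266.1 CPM in the other libraries. Library 1 held more olfactory receptor reads than library 2 in every group. The levels were 2544 and 1418 CPM in sgSCR 1 and 2, 1330 and 380 in sgMif, 1514 and 523 in shSCR, and 2362 and 553 in shMif. The division thus partly follows the replicate number, though the cut at 1000 CPM puts both sgSCR libraries in the high class. The labels give no batch, so the origin of the division stays open.

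For the joint effect of the Mif labels, 34 splits of the 8 libraries into 4 and 4 could be fitted beside the system term. The real split gave 0 calls by edgeR (279 by DESeq2), a count that no split can fall below, so the splits were compared by their genes at an unadjusted p under 0.05. The real split had 1306, and 8 of the 34, itself included, had as many, so chance cannot be excluded. The highest other split had 2715, and set both sgMif libraries, shMif 2 and shSCR 2 against the rest, which within the shRNA libraries follows the olfactory class.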
